A study of Arabidopsis thaliana with 12 samples.

How the data were processed

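RNA was measured in leaves of 18-day-old Arabidopsis thaliana plants, per the labels, on 12 Agilent 1-colour (Cy3) arrays, 1 array per sample with 200 ng of RNA. The samples form 4 groups of 3 arrays: wild type (WT, accession La-0) and plants expressing a constitutively active form of the MAP kinase kinase kinase YODA (CA-YDA), each mock-treated with water or inoculated with spores of the fungus Plectosphaerella cucumerina isolate BMM (PcBMM). All were taken 1 day after treatment in 3 independent experiments. The labels give the La-0 background for both lines.

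Per the file headers, the scanner files hold spot intensity from Agilent Feature Extraction 10.7.3.1. The processed signal used here is a background-subtracted and detrended intensity, not normalized between arrays by the authors. Other deposited columns used were the mean pixel signal and the median local background, both as intensity. The deposited spot marks (well above background, saturated, non-uniform, population outlier) are other values, coded 0 or 1. The authors also deposited a value table in log2 units, which all 12 columns show to be quantile normalized: each had a minimum of 5.745, a maximum of 19.246 and a median between 9.001 and 9.003. How that table was computed was not stated, and it was used only as an alternative.

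Each array held 45220 spots, of which 43803 were not controls, and 43603 different probes. The share of spots well above background was 64.29 to 72.16%, the 75th percentile of the signal was 1885 to 3462 and 0 spots were saturated. Replicate arrays of a group correlated at r = 0.9563 to 0.9871 across the tested genes, which are not independent replicates. With 3 arrays per group, the number of arrays limits the precision.

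The processed signal was put on the log2 scale and the array's own 75th percentile over non-control probes was subtracted, so every value is relative to that percentile. Spot values marked as non-uniform or outlying, 11 to 111 per array, were left out, and replicate spots of a probe were averaged. Probes were assigned to genes by the accessions and locus names of the files and a reference gene table. A gene was found for 35909 probes and none for 7689, and 26059 genes had a probe. Probes were kept when well above background on all 3 arrays of at least 1 group. That left 30106 probes, and the brightest probe stood for each of the 19463 genes tested. No reference genome sequence was at hand, so probes were not aligned again. All 12 columns of the value table belonged to samples in use, and 0 were left out.

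Tests used limma 3.58.1 in R 4.3.3, with a model of 4 group means over all 12 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison. Genes with an adjusted p under 0.05 were called. The comparisons were CA-YDA minus WT in mock-treated plants, the same in inoculated plants, PcBMM minus mock in WT, the same in CA-YDA, and the interaction, which is the CA-YDA response minus the WT response. Changes are log2 differences. Where a group had 0 of 3 arrays above background, the change is given as "at least N-fold": the mean of the measured group was compared with the mean of the other after each array's value was raised to at least the lowest signal called well above background on that array. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

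Gene lists were tested with camera, with a preset correlation of 0.01 and again with an estimated one, and adjusted over 105 tests. The 21 lists covered stomatal lineage, guard cell, YDA cascade, salicylic acid, jasmonate, ethylene and defensin, antimicrobial peptide, tryptophan-derived metabolites, aliphatic glucosinolate, pattern-triggered immunity, cell wall, lignin and phenylpropanoid, flavonoid and anthocyanin, photosynthesis (mesophyll), abscisic acid and drought, cell division, trichome and epidermis, vascular, senescence, detoxification and oxidative stress, and circadian clock. Of 431 listed members, 422 matched a gene by code and name. For each list, calls are given over all genes tested and adjusted over the list alone. Overlaps were counted per direction, and correlations of log2 changes are across genes. Where comparisons shared arrays, 50 simulations of unchanged groups gave the covariance due to sharing.

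The comparisons, tests, filters, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took YDA first; per comparison the 6 largest rises and 6 largest falls among called genes with a symbol whose groups of 3 arrays did not overlap; from lists with at least 3 called genes the 3 with the smallest adjusted p; and the markers PR1, PR2, PDF1.2a, VSP2, PAD3, SPCH, TMM and MYB60. For the interaction it took the 5 with the smallest adjusted p. Several departures were chosen after values were seen. Largest rises and falls were taken among genes measured in both groups, and genes measured in only 1 group were ranked apart by their bound; lists with fewer than 3 called genes contributed named members too, as did further called genes of the interaction. The test of gene families by symbol, the comparison of replicate 1 with the others and 3 added alternatives were also chosen after the data were seen.

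The method was tested on simulated data with the spread of these arrays. A change of 2 log2 units was recovered for 86 to 91% of genes in the comparisons of 2 groups and for 42% in the interaction. A change of 1 was recovered for 14 to 27% and 0%, and false calls were 2.3 to 6.2% of calls. Camera called 0 of 20 unchanged lists. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes vary together.

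Per the file headers, the arrays lay on 4 slides. WT replicates 1 and 2 of both treatments shared a slide, as did WT replicate 3 of both treatments, and the CA-YDA arrays were laid out likewise on the other slides. Genotype was therefore never compared within a slide, while mock and PcBMM always were. Replicate numbers also tied samples together: after group means were removed, the 18 pairs of arrays with the same number correlated at a mean r of 0.395 and the 36 other pairs at -0.185, across genes. With group means removed, the second value largely follows from the first and is no separate evidence. Pairs of replicates 2 and 3 were positive too (0.014 to 0.284), so much of the tie lay in replicate 1. Counts with replicate number as a fixed block are therefore given beside the main counts. The standard errors and adjusted p of single genes are from the model without that block. The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, blocks for replicate and slide, the authors' value table, the mean of a gene's probes, stricter thresholds, trended and robust moderation, fits of only the 2 groups compared, and leaving out each array.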

Results

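Transcripts of 19463 genes were compared on 12 arrays in 4 groups of 3: WT mock, WT PcBMM, CA-YDA mock and CA-YDA PcBMM. PcBMM is a necrotrophic leaf pathogen, and YODA is a MAP kinase kinase kinase known for its part in stomatal patterning and embryo development. The first component of a principal component analysis of 19165 genes held 49.5% of the variance and separated inoculated from mock-treated plants. The next held 25.1% and separated the genotypes, and component 3 held 11% and set replicate 1 apart from replicates 2 and 3. As the genotypes lay on different slides, the component with 25.1% parts those slides in the same way. Between 64.29 and 72.16% of the spots of an array were well above background. Changes are log2 differences over n = 3 arrays per group, with the limma standard error (SE) after ±.

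**Figure D1:**
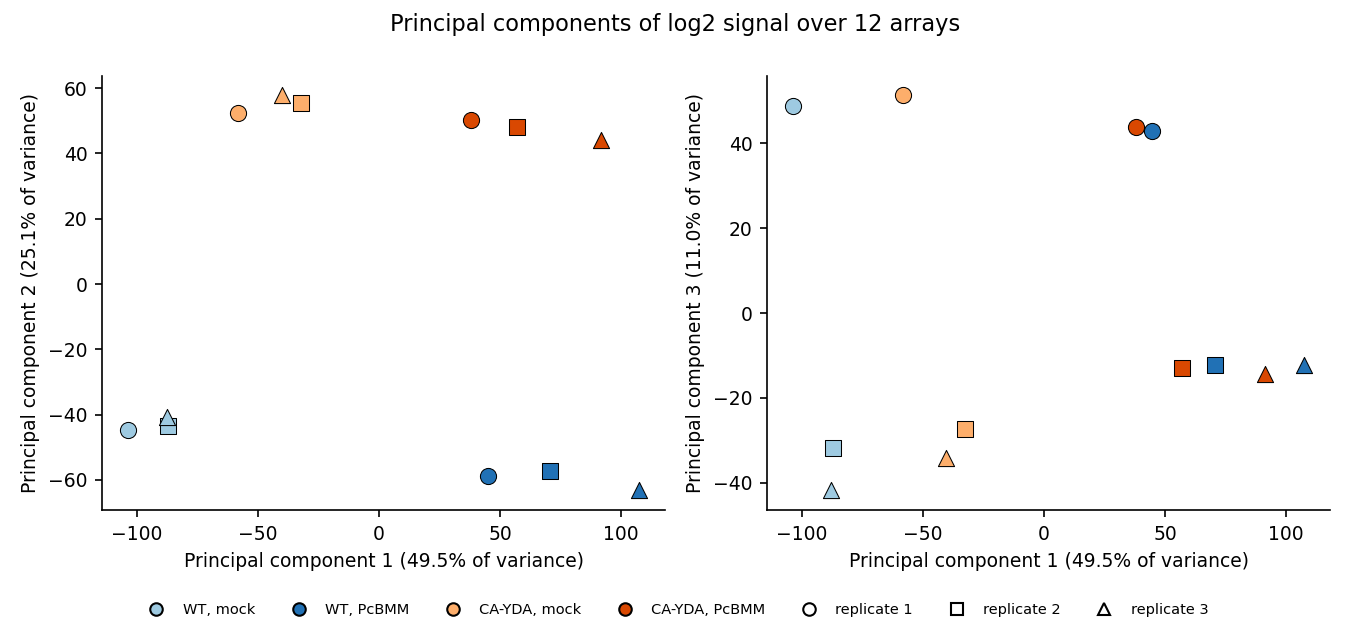
Principal components 1 to 3 of the 12 arrays, with the percent of variance on each axis; each point is an array, colour gives the group and shape the replicate. Component 1 (49.5%) parts mock from PcBMM, component 2 (25.1%) parts the genotypes, which lay on different slides, and component 3 (11%) parts replicate 1 from the others.

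YDA (AT1G63700) was read by a probe on chromosome 1, positions 23625323 to 23625264 on the TAIR10 build. Relative to the array's 75th percentile, its log2 signal was 1.26 ± 0.095 (SD, n = 3) in CA-YDA mock, 1.15 ± 0.217 in CA-YDA PcBMM, -1.18 ± 0.257 in WT mock and -1.89 ± 0.051 in WT PcBMM. Replicates 1 to 3 read 1.292, 1.336 and 1.154 in CA-YDA mock and 0.985, 1.066 and 1.395 in CA-YDA PcBMM. The WT values were -1.423, -1.205 and -0.911 in mock and -1.912, -1.925 and -1.831 after PcBMM. YDA was higher in CA-YDA by 2.44 ± 0.192 in mock-treated plants (adjusted p = 6.61e-06) and by 3.04 ± 0.192 in inoculated plants (adjusted p = 1.02e-06). After inoculation it fell by 0.71 in WT (adjusted p = 0.0177), and the change of -0.11 in CA-YDA did not pass (adjusted p = 0.767). The interaction of 0.60 did not pass either (adjusted p = 0.664). The arrays do not tell native from introduced YDA transcripts.

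The question of the comparison between mock-treated genotypes was what constitutively active YDA changes without the fungus. In uninfected CA-YDA leaves many defence genes were higher than in WT. The thionin gene THI2.2 was higher by 7.80 ± 0.565 (adjusted p = 3.84e-06), PCC1, a pathogen-responsive gene, by 4.45 ± 0.457, and the immunity marker NHL10 (YLS9) by 4.27 ± 0.342. Unlike PCC1 and NHL10, THI2.2 did not rise with PcBMM. Its mean log2 signal was -5.49 in WT mock, -5.80 in WT PcBMM, 2.31 in CA-YDA mock and 1.33 in CA-YDA PcBMM. Its genotype difference was thus not one of a gene induced by the fungus here. PR1, a marker of salicylic acid signalling, was higher by 3.44 ± 0.701 (adjusted p = 0.00913), and CYP71A13 and PAD3, which act in synthesis of the phytoalexin camalexin, by 3.30 ± 0.393 and 2.79 ± 0.349. The stomatal genes SDD1, MUTE and EPF1 were lower, by -1.99 ± 0.338, -1.70 ± 0.347 and -1.37 ± 0.34. In all, 1037 genes were higher and 615 lower (1657 and 1095 with replicate as a block).

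Among genes measured in both groups, the largest rises were THI2.2, the metacaspase MC8 (5.99), the cytochrome P450 CYP89A5 (5.66), the sulfur-deficiency gene LSU2 (5.05), PCC1 and CYP81G1 (4.31). The largest falls were XRCC4, which acts in DNA end joining (-7.49), the metal pump HMA1 (-7.11), the peroxiredoxin gene TPX2 (-6.11), TBL37 (-6.01), the inositol oxygenase MIOX1 (-5.90) and FKF1, a blue-light receptor of the flowering pathway (-4.71). Several rested on partly measured groups. XRCC4 and MIOX1 were above background on 1 of 3 CA-YDA mock arrays and HMA1 on 2, while on the WT mock side THI2.2, MC8, NHL10 and PR1 were above it on 2 of 3 and CYP81G1, CYP71A13, WRKY38, GSTU4 and THI2.1 on 1. A further 155 higher and 109 lower genes were above background on 0 arrays of 1 group. Those higher in CA-YDA included emb2731 (at least 130-fold), the immune receptor DAR4 (at least 113-fold), LUL1 (at least 50.8), EXO84B (at least 50.1) and the receptor kinases CRK14 (at least 48.7) and SERK5 (at least 33.7). Lower in CA-YDA were the flowering repressor MAF1 (at least 192-fold), TTN10 (at least 52.5), MEE22 (at least 19.4), CYP705A9 (at least 18.6), NSP4 (at least 13.9) and the resistance gene RPM1 (at least 13.3-fold). Probes of a gene could differ: another SERK5 probe read 0.10, and the fitted values of the 3 MAF1 probes, -1.82, -9.33 and -7.66, rest partly on CA-YDA signals below background. For probes over 4-fold apart between the genotypes in both treatments, all kept probes followed in 65 of 172 genes, or 37.8%. The share was 87.8% for probes changed by PcBMM in WT. A large genotype difference read by 1 probe therefore need not be a difference in transcript level.

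Of the 26 salicylic acid genes tested, 16 were higher, 0 lower and 10 did not pass (21 higher adjusted over the list alone), among them WRKY38 (3.43), CBP60g (3.09) and PR2 (BGL2; 1.68, adjusted p = 0.0253). The list was called up by camera with an adjusted p of 2.59e-15, and with adjusted p = 0.146 with an estimated correlation. Pattern-triggered immunity genes were higher for 8 of 34 (12 higher and 1 lower adjusted over the list alone), with NHL10, the kinase MPK11 (2.82) and PROPEP3, a danger peptide precursor (at least 5.11-fold); camera gave adjusted p = 3.03e-05 and, with an estimated correlation, adjusted p = 0.511. For tryptophan-derived metabolites, 7 of 28 were higher (9 higher and 1 lower adjusted over the list alone), with CYP71A13, PAD3 and the glucosinolate regulator MYB51 (1.54); the adjusted p was 0.000147 and 0.502 with an estimated correlation. Ethylene and defensin genes were higher for 4 of 21 (6 adjusted over the list alone), with the chitinase gene PR3 (HCHIB; 2.87) and the ethylene response factor ERF2 (1.58); the adjusted p was 0.0041 and 0.368 with an estimated correlation. PDF1.2a, a defensin marker of this group, read 2.22 ± 0.812 and did not pass (adjusted p = 0.134). Jasmonate genes were higher for 3 of 27 (4 adjusted over the list alone), which were VSP1 (1.78), VSP2 (1.76) and TAT3 (1.89); the adjusted p was 0.00626 and 0.635 with an estimated correlation. Detoxification genes were higher for 4 and lower for 1 of 17 (7 and 2 adjusted over the list alone), with the glutathione transferases GSTU4 (4.00) and GSTF7 (2.12) higher and GSTU24 (-2.43) lower; the adjusted p was 0.0472 and 0.619 with an estimated correlation.

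Guard cell genes moved down in camera (adjusted p = 0.000517, and adjusted p = 0.0995 with an estimated correlation). Of 14, CHX20 (-1.22), ABCG22 (-1.06) and the kinase OST1 (-0.85) were lower and the myrosinase TGG1 (0.75) higher; 6 were lower and 1 higher adjusted over the list alone. Another ABCG22 probe read 3.01, and the mean of the kept probes was 0.98 (adjusted p = 0.0736). Vascular genes also moved down (adjusted p = 5.38e-05, and adjusted p = 0.0995 with an estimated correlation): the vascular regulator HB-8 (-0.93) and the sugar transporters SUC2 (-0.89) and SWEET11 (-0.86) were lower, 3 of 10, or 5 adjusted over the list alone. Of 18 stomatal lineage genes only SDD1, MUTE and EPF1 were lower, 3 also adjusted over the list alone (adjusted p = 0.359 in camera, 0.764 with an estimated correlation). The lineage markers SPCH (-0.10, adjusted p = 0.913) and TMM (-0.02, adjusted p = 0.984) and the guard cell marker MYB60 (-0.42, adjusted p = 0.287) did not pass.

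The other lists did not pass in camera. Higher were 3 of 20 aliphatic glucosinolate genes (MYB29 1.84, MAM1 1.48, BAT5 1.44, with another BAT5 probe at -0.92), 3 of 12 antimicrobial peptide genes (THI2.2, PDF2.5 1.81, THI2.1 1.79) and 4 of 26 cell wall genes, with the pectin methylesterases PME17 (2.42) and PME3 (0.83) and the wall-associated kinase WAK2 (1.14). Their counts adjusted over the list alone were 4, 3 and 6, all higher. Cell division genes CDKB1;2 (2.81) and PCNA2 (1.22) were higher, 2 of 28, as were the lignin gene COMT1 (OMT1; 1.01), the anthocyanin regulator PAP1 (1.86) and, in the YDA cascade list, YDA alone of 7 (2 adjusted over the list alone). The clock gene FKF1 (1 of 14) and the abscisic acid regulator ABF3 (-0.84, 1 of 24) were lower. No senescence, photosynthesis or trichome gene passed: 0 of 10, 0 of 34 and 0 of 13. Every WT array lay on other slides than every CA-YDA array, so genotype and slide could not be separated in this comparison. Without WT mock replicate 2, 385 genes were lower.

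The comparison between inoculated genotypes asked which transcripts differed 1 day after PcBMM. In infected leaves CA-YDA no longer stood above WT in salicylic acid genes: FMO1, which makes the systemic immune signal N-hydroxypipecolic acid, was lower by -2.35 ± 0.444 (adjusted p = 0.00647), and NIMIN1 and ICS1 (EDS16), which makes salicylic acid, by -1.39 ± 0.331 and -1.15 ± 0.302. The thionin gene THI2.2 remained higher in CA-YDA, by 7.12 ± 0.565, and so did the receptor kinase gene CRK14, by 7.53 ± 0.621. SDD1 (-2.25) and MUTE (-1.75) were lower again. In all, 807 genes were higher and 642 lower (1385 and 1196 with replicate as a block). Of these, 483 were also higher and 366 also lower in mock-treated plants, where independent calls would give 43 and 20.3, and 11 were higher in mock and lower in inoculated plants. Both comparisons set the same slides and lines against each other. A slide difference or a sequence difference under a probe would recur in both, so the overlap need not be an effect of YDA. Log2 changes in the mock and inoculated comparisons correlated at r = 0.70 (Spearman 0.457) across genes, which are not independent replicates.

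Besides CRK14 and THI2.2, the largest rises among genes measured in both groups were CYP81G1 (6.16), the receptor-like protein RLP12 (5.65), SERK5 (5.60, with another probe at -4.34) and LSU2 (4.86). The largest falls were TBL37 (-6.09), FKF1 (-4.54), PCR1 (-4.38), ORP4C (-4.15), the wall-associated kinase-like WAKL6 (-4.13) and RBK2 (-3.30). CRK14 and RLP12 were above background on 1 of 3 WT PcBMM arrays and THI2.2 on 2; RBK2 was above it on 1 of 3 CA-YDA PcBMM arrays and FKF1, WAKL6 and ORP4C on 2. A further 90 higher and 133 lower genes were above background on 0 arrays of 1 group. Higher were emb2731 (at least 188-fold), DAR4 (at least 157), CRK15 (at least 93.5), EXO84B (at least 78.2), LUL1 (at least 53.3) and CYP71B37 (at least 13-fold, with another probe at 0.17 on the log2 scale). Lower were HMA1 (at least 260-fold), XRCC4 (at least 207), MAF1 (at least 152), the receptor-like proteins RLP38 (at least 137) and RLP11 (at least 87.6), and TTN10 (at least 37.5). The limit given for large genotype differences in mock-treated plants, that other probes of a gene often did not follow, holds here too.

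Salicylic acid genes were lower for 3 of 26, the same number adjusted over the list alone, and higher for 0 (camera down, adjusted p = 0.00219, and adjusted p = 0.532 with an estimated correlation). PR1 (1.37, adjusted p = 0.313) and PR2 (-0.23, adjusted p = 0.836) did not pass. Tryptophan-derived metabolite genes passed for 0 of 28 and moved down as a list (adjusted p = 0.00508, and adjusted p = 0.539 with an estimated correlation), with PAD3 at -0.11 (adjusted p = 0.917). Guard cell genes moved down (adjusted p = 0.00707, and adjusted p = 0.128 with an estimated correlation): CHX20 (-1.09) and OST1 (-0.88) were lower and TGG1 (0.87) higher, or 5 lower and 1 higher of 14 adjusted over the list alone. Vascular genes moved down (adjusted p = 0.0317, and adjusted p = 0.189 with an estimated correlation) with 0 of 10 called, or 1 lower adjusted over the list alone. Of 34 pattern-triggered immunity genes, 1 was higher, PROPEP1 (1.77), and 4 lower, among them RLP30 (-1.44) and the ubiquitin ligase PUB24 (-1.05); the list gave adjusted p = 0.0709. Detoxification genes were split, with GSTU25 (2.65) among 2 higher and GSTU24 (-3.00) and UGT73B5 (-2.86, with another probe at -0.94) among 3 lower of 17.

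The remaining lists did not pass in camera either. Cell wall genes were higher for 3 of 26, PME3 (0.90), the cellulose synthase CESA6 (0.98) and XTH33 (1.67), and lower for 1, PGIP1 (-1.26). MYB29 (1.75), MAM1 (1.59) and BAT5 (1.39, with another probe on the other side of 0) were higher, 3 of 20 aliphatic glucosinolate genes. Of 28 cell division genes CDKB1;2 (2.53) and CYCD3;2 (1.39) were higher and MCM6 (-0.76) lower. In the jasmonate list JAZ3 (1.01) was higher and TAT3 (-1.96) lower of 27, and VSP2 read 1.29 (adjusted p = 0.0547). For ethylene and defensin 1 of 21 was higher, with PDF1.2a at 2.86 (adjusted p = 0.0555). Single genes passed elsewhere: THI2.2 of 12 antimicrobial peptide genes, PAP1 (2.27), GL1 (MYB0; 1.52) and COR47 (1.02) were higher, and CCOAOMT1 (-1.02), SEN1 (-1.41), RAB18 (-1.47) and FKF1 lower. SDD1 and MUTE were the 2 lower of 18 stomatal lineage genes (adjusted p = 0.933), with SPCH at -0.45 (adjusted p = 0.458), TMM at 0.33 (adjusted p = 0.68) and MYB60 at -0.60 (adjusted p = 0.108); YDA alone passed of 7 YDA cascade genes and 0 of 34 photosynthesis genes did. Adjusted over the list alone, 3 jasmonate, 2 ethylene and 3 antimicrobial peptide genes were higher, 1 stomatal lineage gene was higher and 3 lower, and 5 pattern-triggered immunity, 2 lignin and 2 senescence genes were lower; the counts of the other lists were as over all genes. Genotype and slide could not be separated here. The counts fell to 500 higher and 412 lower without CA-YDA PcBMM replicate 2, to 535 and 363 without WT PcBMM replicate 2, and to 512 and 417 without WT PcBMM replicate 3.

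**Figure D2:**
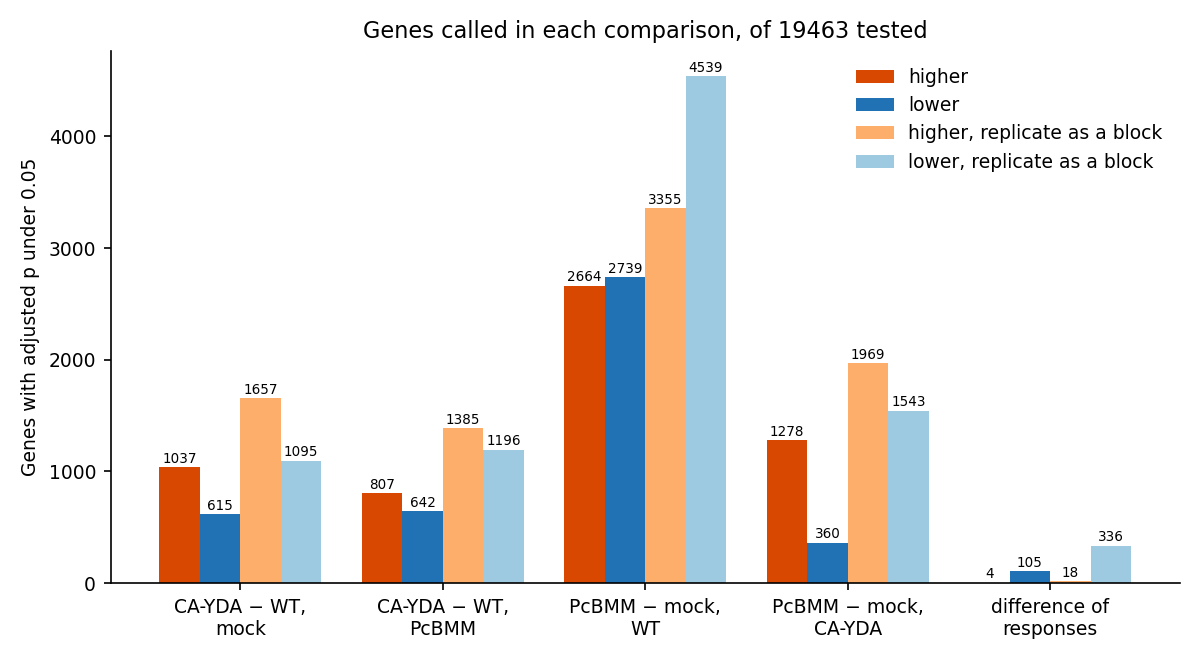
Number of genes with an adjusted p under 0.05 (y axis) in each comparison (x axis), as bars for genes higher and lower, without and with replicate number as a block. The WT response was largest, with 2664 genes higher and 2739 lower, against 1278 and 360 in CA-YDA.

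The WT response to PcBMM asked how wild-type leaves had changed 1 day after inoculation. All 26 salicylic acid genes and most genes of tryptophan-derived metabolites and pattern-triggered immunity on the lists rose. FMO1 rose by 10.43 ± 0.444 (adjusted p = 5.88e-08), the camalexin genes CYP71A13 and PAD3 by 10.34 ± 0.393 and 8.32 ± 0.349, NHL10 by 9.80 ± 0.342 and PR1 by 4.35 ± 0.701. Of 34 photosynthesis genes 10 fell, such as PRK, an enzyme of the Calvin cycle (-1.43 ± 0.31), and of 18 stomatal lineage genes 7, such as the receptor kinase gene ER (-1.15). In all, 2664 genes rose and 2739 fell (3355 and 4539 with replicate as a block). The median of all genes was -0.185, and between -0.185 and -0.128 under the other scalings, and the falls given below include that shift.

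The largest rises among genes measured in both groups were UGT76B1, a glucosyltransferase acting on immune signals (10.98), FMO1, CYP71A13, NHL10, the transporter ABCG40 (9.05) and GSTU11 (8.60). UGT76B1, FMO1, CYP71A13, WRKY38 and WAKL10 were above background on 1 of 3 WT mock arrays and NHL10, GSTU11, NIMIN1 and PR1 on 2. The largest falls were the arabinogalactan protein AGP3 (-3.27), UMAMIT4 (-2.67), the desaturase ADS1 (-2.42), the phosphatase PAP16 (-2.31), MLP329 (-2.29) and BZIP34 (-2.28). A further 296 genes were above background only after inoculation, with BAP2 (at least 206-fold), ALD1, which makes pipecolic acid (at least 133), PROPEP3 (at least 112), the lipase GLIP1 (at least 86.1), GLP9 (at least 76.9) and RABA1e (at least 75.5) at the top. Another 17 were above background only in mock-treated plants, with EXO70H3 (at least 6.89-fold), HDG8 (at least 4.33) and UMAMIT36 (at least 1.91, from 2 of 3 WT mock arrays).

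All 26 salicylic acid genes rose (26 adjusted over the list alone), with WRKY38 (8.53), NIMIN1 (7.34) and PR2 (2.39); camera gave adjusted p = 1.08e-25, and adjusted p = 0.0995 with an estimated correlation. Of 28 tryptophan-derived metabolite genes 25 rose (26 rose and 1 fell adjusted over the list alone), with CYP79B2 (5.51); the adjusted p was 2.57e-20 and 0.109 with an estimated correlation. Pattern-triggered immunity genes rose for 26 of 34 (29 adjusted over the list alone), with WAKL10 (6.79); the adjusted p was 1.13e-17 and 0.197 with an estimated correlation. Detoxification genes rose for 14 of 17 (15 adjusted over the list alone), with GSTF7 (6.95), CYP81D8 (5.06) and UGT73B5 (4.45); the adjusted p was 4.54e-12 and 0.128 with an estimated correlation. Jasmonate genes rose for 15 of 27 (16 adjusted over the list alone), with TAT3 (8.49), the jasmonate-catabolic gene CYP94C1 (3.30) and the biosynthesis gene LOX2 (3.16); the adjusted p was 1.06e-06 and 0.502 with an estimated correlation. VSP2 read -0.60 (adjusted p = 0.242). Ethylene and defensin genes rose for 11 of 21 (13 adjusted over the list alone), with ERF1 (4.66), the ethylene biosynthesis gene ACS2 (at least 74.3-fold), PDF1.1 (LCR67; at least 23-fold) and PDF1.2a (2.68, adjusted p = 0.0294); the adjusted p was 1.83e-05 and 0.166 with an estimated correlation.

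Photosynthesis genes fell for 10 of 34 (15 adjusted over the list alone), with PRK and PSAH2 (-1.08); camera gave adjusted p = 0.000111, and adjusted p = 0.527 with an estimated correlation. Stomatal lineage genes fell for 7 of 18 (8 adjusted over the list alone), with ER, FLP (-1.18), HDG2 (-0.89) and ERL2 (-0.88); the adjusted p was 0.0108 and 0.502 with an estimated correlation. SPCH (-0.78, adjusted p = 0.0675), TMM (-0.44, adjusted p = 0.366) and MYB60 (-0.44, adjusted p = 0.129) did not pass. Trichome and epidermis genes fell for 4 of 13, also adjusted over the list alone, with GL1 (-1.11) and the wax genes CER3 (-1.06) and CER1 (-0.91); the adjusted p was 0.0479 and 0.511 with an estimated correlation. Cell wall genes went both ways: 7 rose, with WAK3, PME17 (6.08), WAK1 (4.42) and the polygalacturonase inhibitor PGIP1 (4.41), and 8 fell, with CESA3 (-1.16), of 26.

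Other lists did not pass in camera. Lignin genes rose for 4 and fell for 2 of 15, with CCR2 (3.94) and COMT1 (2.39) higher and PAL4 (-1.17) lower. The senescence genes WRKY6 (2.89), NAP (2.44) and NYE1 (0.98) were among 4 of 10 that rose. Abscisic acid genes rose for 2 of 24, with NCED3 (2.72), and fell for 6, with COR47 (-1.60), KIN2 (-1.24) and ABF3 (-1.08). Of 12 antimicrobial peptide genes the defensin gene PDF1.4 rose and 4 fell, with GASA6 (-2.18); of 10 vascular genes SWEET12 (1.04) rose and 4 fell, with HB-8 (-0.92) and SWEET11 (-0.89); and of 14 clock genes TOC1 (1.03) rose and 3 fell, with GRP7 (-1.09), RVE8 (-0.69) and FKF1 (-0.57). In the YDA cascade list of 7, MKK9 (1.96) rose and MKK7 (-1.28) and YDA fell. SOT17 (1.45) rose and GSTF11 (-1.29) fell of 20 aliphatic glucosinolate genes, TGG1 (-0.52) fell of 14 guard cell genes, CYCD3;1 (-0.84) fell of 28 cell division genes, and 0 of 6 flavonoid genes passed. Adjusted over the list alone, 11 cell wall genes fell, 5 lignin genes and 5 senescence genes rose, 3 abscisic acid genes rose and 8 fell, 2 YDA cascade genes rose and 0 guard cell genes passed; the other counts here were as over all genes. Within slides, 1678 genes rose and 493 fell on slide 1, and 1653 and 1062 on slide 2, which held replicate 3 alone, so that 1 array per group was compared with the spread taken from slides 1 and 3. The number that fell was 1573 without WT mock replicate 2, 1681 without WT mock replicate 3, 1615 without WT PcBMM replicate 2 and 942 without WT PcBMM replicate 3.

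**Figure D3:**
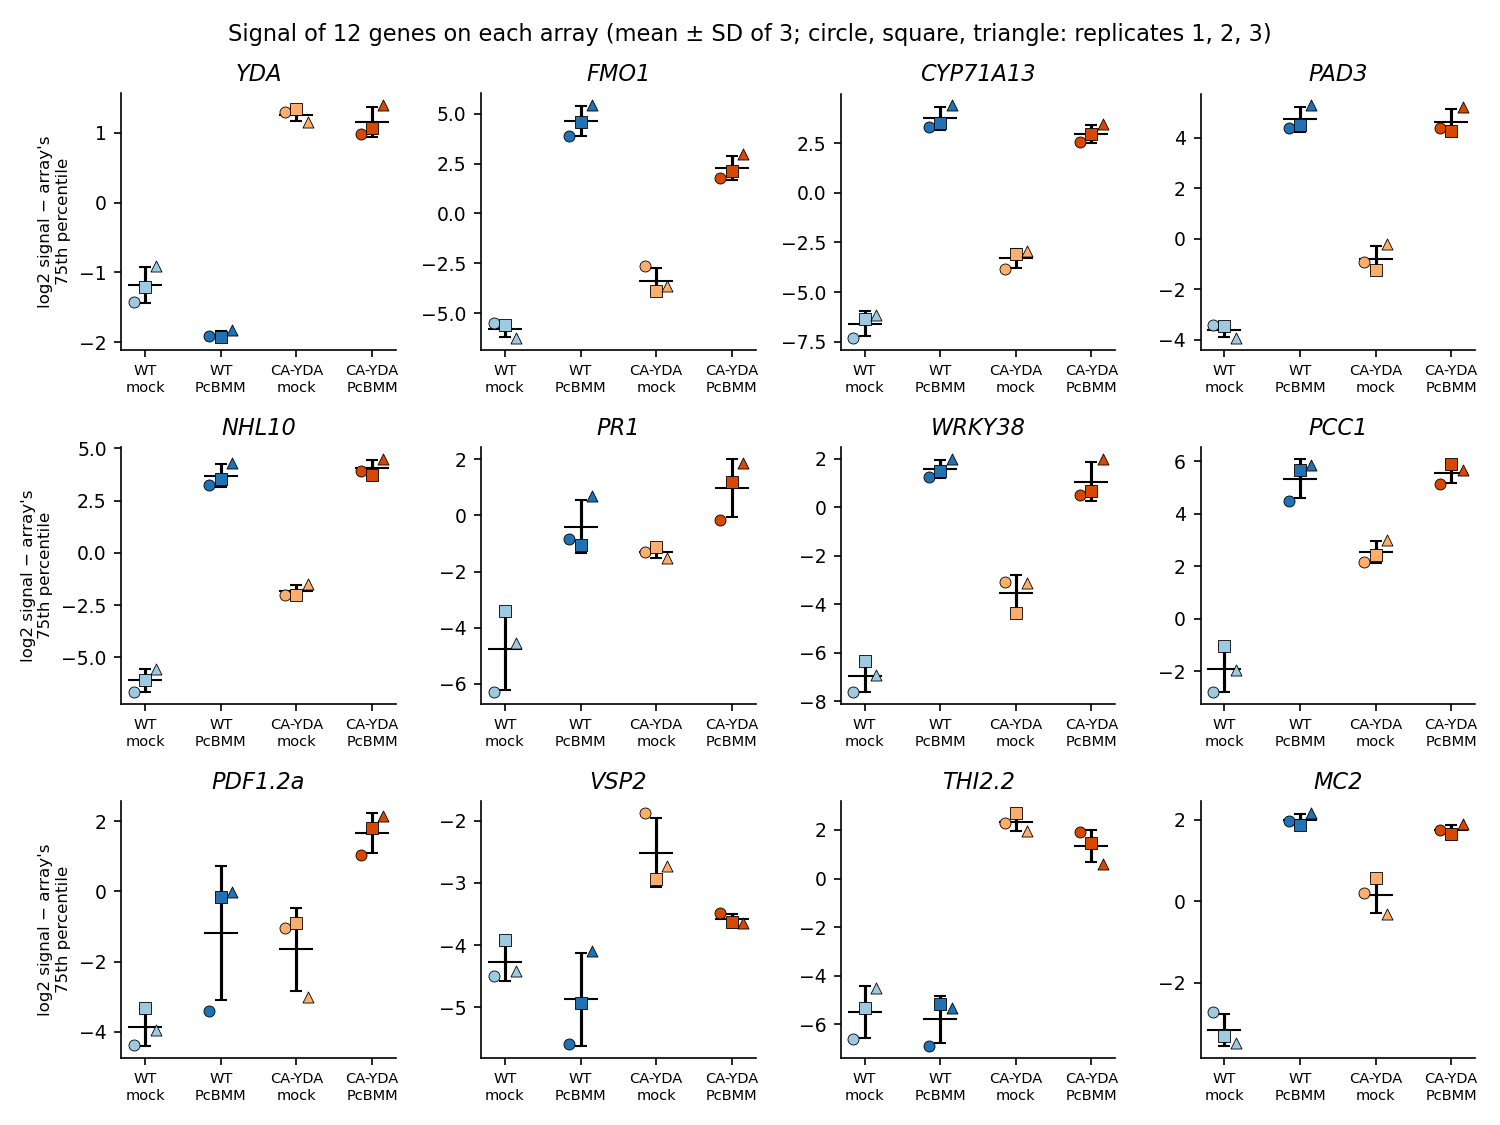
Log2 signal minus the array's 75th percentile (y axis) for 12 genes in the 4 groups (x axis); points are arrays, with shapes for replicates 1, 2 and 3, and bars give the mean ± SD of 3. FMO1 and CYP71A13 start higher in CA-YDA mock (-3.40 and -3.29) than in WT mock (-5.79 and -6.60), and after PcBMM CYP71A13 reaches 2.97 in CA-YDA and 3.74 in WT.

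The CA-YDA response to PcBMM asked the same of plants with active YODA. Many defence genes rose here too, with CYP71A13 up by 6.27 ± 0.393 (adjusted p = 6.44e-06), NHL10 by 5.88 ± 0.342, FMO1 by 5.70 ± 0.444 and PAD3 by 5.42 ± 0.349. The defensin gene PDF1.2a rose by 3.32 ± 0.812 (adjusted p = 0.0263). PR1 read 2.28 ± 0.701 and did not pass (adjusted p = 0.0677), nor did PR2 at 0.49 (adjusted p = 0.507). In replicates 1 to 3 PR1 read -1.305, -1.113 and -1.523 in CA-YDA mock and -0.157, 1.184 and 1.88 in CA-YDA PcBMM. PR1 was thus higher after PcBMM in each replicate, and the missing call does not show that it was unchanged. In all, 1278 genes rose and 360 fell (1969 and 1543 with replicate as a block). Of these, 1223 also rose and 293 also fell in WT, where independent calls would give 174.9 and 50.7, and 1 gene went opposite ways; the changes correlated at r = 0.888 (Spearman 0.782) across genes. The median of all genes was -0.113, and between -0.111 and -0.073 under the other scalings.

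Among genes measured in both groups the largest rises were UGT76B1 (7.53), the peroxidase PER4 (7.44), ABCG40 (6.79), CYP71A13, NHL10 and GLIP1 (5.88). The largest falls were AGP3 (-2.97), GASA6 (-1.95), the wall enzyme XTH33 (-1.86), RTFL6 (-1.79), the dormancy gene DOG1 (-1.76) and the kinase CIPK20 (-1.68). PER4, ACS2 and PROPEP2 were above background on 1 of 3 CA-YDA mock arrays and GLIP1 on 2, and AGP3 was above it on 2 of 3 CA-YDA PcBMM arrays. A further 142 rose and 13 fell with 0 arrays of 1 group above background. Those that rose included PDF1.1 (at least 31.3-fold), EXO70H1 (at least 29.6), the metalloproteinase MMP (at least 17.1), RSH4 (at least 16.1), CRK13 (at least 15.2) and UGT73D1 (at least 12.4). NPY4 (at least 2.59-fold), SCPL32 (at least 2.4) and HDG8 (at least 1.96, from 2 of 3 CA-YDA mock arrays) fell.

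Tryptophan-derived metabolite genes rose for 20 of 28 (23 adjusted over the list alone), with CYP83B1 (2.73); camera gave adjusted p = 9.17e-23, and adjusted p = 0.0995 with an estimated correlation. Salicylic acid genes rose for 19 of 26 (22 adjusted over the list alone), with WRKY38 (4.57) and NIMIN1 (3.94); the adjusted p was 5.72e-21 and 0.109 with an estimated correlation. Pattern-triggered immunity genes rose for 15 of 34 (24 adjusted over the list alone), with PROPEP2 (5.09) and PROPEP3 (4.36); the adjusted p was 7.21e-17 and 0.206 with an estimated correlation. Detoxification genes rose for 11 of 17 (15 adjusted over the list alone), with GSTU24 (5.20), GSTF7 (4.26) and CYP81D8 (3.62); the adjusted p was 2.91e-12 and 0.128 with an estimated correlation. Ethylene and defensin genes rose for 9 of 21 (10 adjusted over the list alone), with ACS2 (5.12) and ERF1 (2.73); the adjusted p was 4.17e-06 and 0.146 with an estimated correlation. Jasmonate genes rose for 4 of 27 (9 rose and 2 fell adjusted over the list alone), with TAT3 (4.64), LOX2 (2.81) and AOC1 (1.90); the adjusted p was 6.38e-06 and 0.502 with an estimated correlation. VSP2 read -1.07 (adjusted p = 0.0962).

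Photosynthesis genes moved down in camera (adjusted p = 4.14e-05, and adjusted p = 0.511 with an estimated correlation), with CA1 (-1.10) and PSBO2 (-1.01) the 2 of 34 that fell. SPCH, a master regulator of the stomatal lineage, fell by 1.13 (adjusted p = 0.0354), the only called gene of 18; the list gave adjusted p = 0.0115, and adjusted p = 0.502 with an estimated correlation. TMM (-0.09, adjusted p = 0.902) and MYB60 (-0.62, adjusted p = 0.0827) did not pass. CER3 (-1.07) fell of 13 trichome and epidermis genes, or 2 adjusted over the list alone; the adjusted p was 0.0384 and 0.511 with an estimated correlation. Cell wall genes rose for 5 of 26, with PME17 (3.40), WAK1 (2.95) and PGIP1 (2.80), and fell for 2. CCR2 and COMT1 (0.85) rose of 15 lignin genes. WRKY6 and PAO (ACD1; 0.79) rose and SEN1 (-1.11) fell of 10 senescence genes. PDF1.4 (1.73) rose and GASA6 fell of 12 antimicrobial peptide genes, and RAB18 (-1.28) and KIN2 (-0.98) fell of 24 abscisic acid genes. No gene passed in the guard cell, YDA cascade, aliphatic glucosinolate, flavonoid, cell division, vascular and clock lists (0 each). Adjusted over the list alone, 6 cell wall genes rose and 4 fell, 5 lignin genes rose and 1 fell, 2 senescence genes rose and 2 fell, 3 abscisic acid genes fell and 1 YDA cascade gene rose. Within slides, 579 genes rose and 20 fell on slide 3, and 839 and 407 on slide 4, again replicate 3 alone with the spread taken from slides 1 and 3, so these are no replicated counts. Without CA-YDA PcBMM replicate 3, 775 rose and 53 fell, and 182, 174 and 120 fell without CA-YDA mock replicates 1, 2 and 3.

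**Figure D4:**
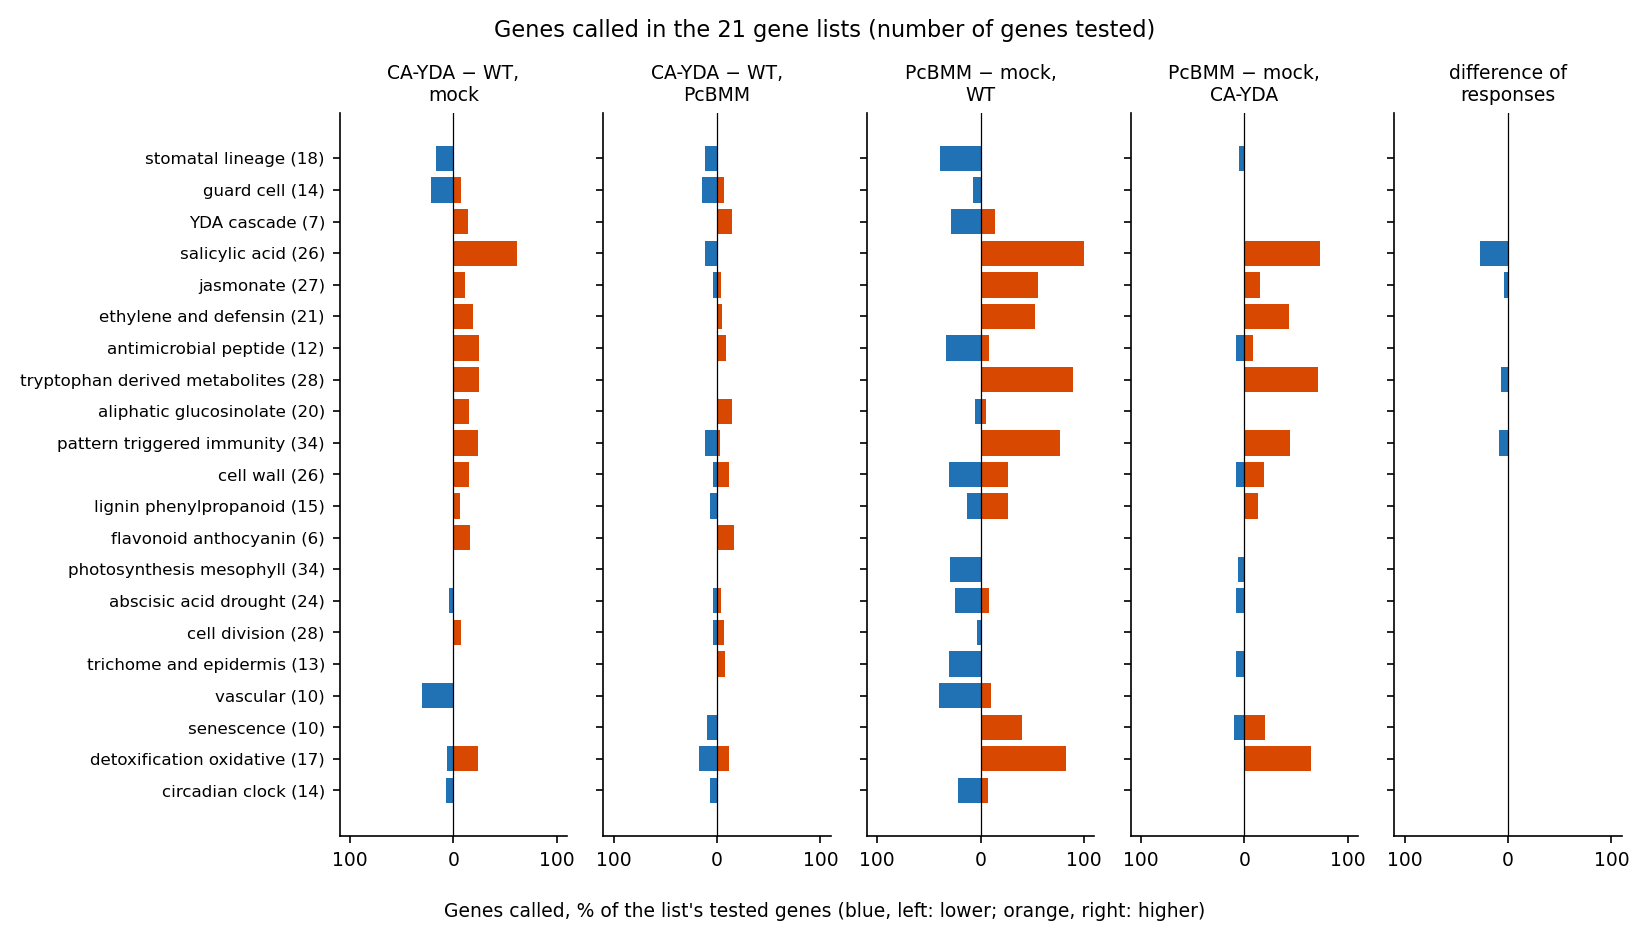
Percent of the tested genes of each of the 21 lists (y axis) that were called higher (orange, right) or lower (blue, left) in each comparison (panels, x axis). The salicylic acid bar covers 26 of 26 genes for the WT response, 19 of 26 for the CA-YDA response and 16 of 26 for mock-treated CA-YDA against WT.

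The interaction asked whether the response to PcBMM differed between the genotypes. FMO1 rose less in CA-YDA than in WT, by -4.74 ± 0.629 (adjusted p = 0.00839), and so did AIG1, named for its induction by avirulent bacteria (-4.37 ± 0.5), the receptor-like kinase gene AT1G51890 (-3.94 ± 0.47), the metacaspase MC2 (-3.56 ± 0.364) and NHL10 (-3.92 ± 0.483). The camalexin genes CYP71A13 (-4.07) and PAD3 (-2.90 ± 0.494, adjusted p = 0.0257) followed. In PAD3 the inoculated levels were near each other, at 4.62 in CA-YDA and 4.73 in WT, and the mock levels were -0.80 and -3.59. Of 109 called genes 105 had a smaller rise or larger fall in CA-YDA and 4 the opposite (18 higher and 336 lower with replicate as a block).

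Of 26 salicylic acid genes 7 were lower in the interaction, ICS1, NIMIN1, SARD1, WRKY38, FMO1, ALD1 and PCC1 (-4.22, adjusted p = 0.0176), and 22 adjusted over the list alone; their median was -2.39, and camera gave adjusted p = 4.8e-31, and adjusted p = 0.0995 with an estimated correlation. Tryptophan-derived metabolite genes were lower for 2 of 28 (9 adjusted over the list alone; adjusted p = 1.18e-12, and adjusted p = 0.166 with an estimated correlation). Pattern-triggered immunity genes were lower for 3 of 34, NHL10, WAKL10 (-3.28, adjusted p = 0.021) and PUB24 (-2.04, adjusted p = 0.0303), or 11 adjusted over the list alone (adjusted p = 2.52e-12, and adjusted p = 0.31 with an estimated correlation). TAT3 (-3.86, adjusted p = 0.0499) was the 1 called of 27 jasmonate genes (adjusted p = 0.00504, and adjusted p = 0.635 with an estimated correlation). No ethylene and defensin gene (0 of 21; adjusted p = 0.0411, and adjusted p = 0.502 with an estimated correlation) or detoxification gene (0 of 17, 2 adjusted over the list alone; adjusted p = 2.18e-06, and adjusted p = 0.284 with an estimated correlation) was called, though both lists moved down. In each of the remaining lists 0 genes were called and camera did not pass; adjusted over the list alone, 2 cell wall genes and 1 lignin gene were lower. PR1 (-2.07, adjusted p = 0.694), PR2 (-1.91, adjusted p = 0.277), PDF1.2a (0.63, adjusted p = 0.972), VSP2 (-0.47, adjusted p = 0.933), SPCH (-0.35, adjusted p = 0.946), TMM (0.35, adjusted p = 0.961) and MYB60 (-0.19, adjusted p = 0.965) did not pass.

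RLP11 had the smallest adjusted p (0.000119) and was above background on 3 WT PcBMM arrays, 1 WT mock array and 0 CA-YDA arrays, so its fitted interaction is no measured size. Among genes chosen after their values were seen, WRKY50 (-3.96), SUFE2 (-3.04) and the cytokinin oxidase CKX4 (-3.02) were also lower. The 4 higher genes were EXO70H3 (adjusted p = 0.00346), AT5G54700, AT2G27270 and the arabinogalactan protein AGP2 (1.98). EXO70H3 was above background only on the 3 WT mock arrays, and AT5G54700 and AT2G27270 only on the 3 CA-YDA PcBMM arrays, so no sizes are given for these. For RLP11 and these genes, a probe that does not read in 1 of the lines would give the same call. Of the genes that rose less in CA-YDA, ALD1 was above background on 0 of 3 WT mock arrays, FMO1, CYP71A13, WRKY38, WAKL10 and WRKY50 on 1, and NHL10, NIMIN1 and AT1G51890 on 2. The count was 46 without CA-YDA mock replicate 2, 34 without CA-YDA mock replicate 3, 37 without CA-YDA PcBMM replicate 1, 33 without CA-YDA PcBMM replicate 2, 55 without WT mock replicate 2, 48 without WT PcBMM replicate 2 and 38 without WT PcBMM replicate 3. It was 143 with slide as a fixed block, 33 for genes above background on all 12 arrays, 9 with normexp background correction and 4 in the authors' value table. The slide block covers only slides within a genotype, since no slide held both genotypes.

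The genes higher in uninfected CA-YDA overlapped the WT response to the fungus. Of 1037 genes higher in CA-YDA mock, 465 also rose after PcBMM in WT, where independent calls would give 141.9, and 65 fell; of the 615 lower genes, 158 fell and 41 rose. NHL10, CYP71A13, PAD3, PR1 and WRKY38 were in the first set. Both comparisons use the WT mock arrays, which alone gave a covariance of 0.06 in simulated unchanged groups; the measured covariance was 0.381, which is 0.321 above it. The simulations called 0 genes in both comparisons, which says little, as unchanged groups give few calls in either, and part of the overlap can come from the shared arrays. Log2 changes correlated at r = 0.378 (Spearman 0.371) across genes, against 0.499 in the simulations, so the correlation itself is no measure of the overlap. Over all lists and comparisons, 36 of 105 camera tests passed with the preset correlation and 0 with an estimated correlation. A list's median, mean and test differed in sign only in tests that did not pass, in the cell wall, cell division, jasmonate, stomatal lineage, abscisic acid, trichome, YDA cascade, clock and antimicrobial peptide lists; cell wall genes, for example, had a median of -0.465 and a mean of 0.432 in the WT response.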

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

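The interaction and list tests were fixed before the data were examined. Of the tests of explanations in this part, those of the dimmer genes and of genes measured on every array were set before their results were seen, and the others afterwards.

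The response to PcBMM differed between the genotypes for 109 genes in a direct test of the difference. The 5 with the smallest adjusted p were RLP11 (-6.09 on the log2 scale), EXO70H3 (3.73), MC2 (-3.56), AIG1 (-4.37) and AT1G51890 (-3.94). The values of RLP11 and EXO70H3 are fitted to groups with 0 arrays above background and are no measured sizes. Both were above background on 0 CA-YDA arrays, so a probe that does not read in that line would give the same calls. Of 145 genes not above background in 1 genotype under both treatments, 3 were called in the interaction too. Lists also differed in camera: salicylic acid (adjusted p = 4.8e-31, and 0.0995 with an estimated correlation), pattern-triggered immunity (2.52e-12, and 0.31), tryptophan-derived metabolites (1.18e-12, and 0.166), detoxification (2.18e-06, and 0.284), jasmonate (0.00504, and 0.635) and ethylene and defensin (0.0411, and 0.502). All 6 moved toward a smaller rise in CA-YDA.

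The smaller response was broad. Over 7023 genes that responded on average over both genotypes, the median size of the log2 change was 1.01 in WT and 0.69 in CA-YDA, and 83.2% responded less in CA-YDA (69.1, 84.6 and 74.9% within replicates 1, 2 and 3). Limits of the scanner were tested: 82.1% of the 3512 dimmer responding genes and 83.4% of the 6157 measured on all 12 arrays still responded less, which speaks against compression of bright signals and against a floor under dim genes as the whole cause. The level already reached in mock-treated CA-YDA plants may account for part: in the direction of the response, the mock genotype difference was 53.8% of the difference between responses at the median. The median genotype difference in that direction was 0.202 in mock-treated and -0.2 in inoculated plants, and such medians need not add up. Noise in the mock arrays enters the mock difference and the difference between responses, so the share of 53.8% is not exact. Over all genes, the mock genotype difference and the WT response had a covariance of 0.381, against 0.06 from the shared WT mock arrays in simulated unchanged groups, so that noise is not the whole of their relation. A smaller response due to the genotype itself, or to less fungus in the leaves, which was not measured, stays open. Every CA-YDA array lay on other slides than every WT array. A difference between slides in the size of the measured response therefore stays open too and cannot be told apart from genotype.

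Other groupings of the arrays were tried. For the interaction, 2 of 100 splits, the real one included, called at least the real 109 genes. Most such splits place treatment and genotype differences in the spread within groups, so they call few genes whatever the real result, and chance is not excluded by them. The other such split called 1362 genes and set all 6 WT arrays against all 6 CA-YDA arrays, so it points to the genotype structure of the samples; the next highest called 2. In a second test the genotype and inoculation effects of each gene were kept, and what an additive fit left was exchanged among the arrays of each replicate number. Over the 19165 genes with a value on every array, 1 of 100 arrangements, the real one, called as many as the real 108, and the highest other called 12, so chance can be excluded at a share of 0.05 in that test. For the comparisons of 2 groups, 10 splits are too few for a share under 0.05. In mock-treated plants the real split called 1652 genes and the highest other 1, in inoculated plants 1449 and 0, in WT 5403 and 0, and in CA-YDA 1638 and 1, so 1 split in each, the real one, called as many. Among the 4 splits that parted all 3 same-number pairs, the highest other was 0 in each comparison.

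Probes without a gene also changed. Of 2813 kept probes with no gene name, 299 differed between the genotypes in mock-treated plants (163 higher and 136 lower in CA-YDA), and 466 changed after PcBMM in WT (240 higher and 226 lower).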

How the results depend on the processing

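The direction of every called named gene but ABCG22 held under the alternatives run; the uncalled TMM, PAD3, PR2, PDF1.2a and SPCH changed sign under some in comparisons where they did not pass. Leaving out replicate 1 of every group, for counts and for named genes, and camera with slide as a block were alternatives added after seeing the data. For ABCG22 in mock-treated plants, the mean of its kept probes was 0.977 (adjusted p = 0.0736) against -1.06 for the brightest, which reversed it because its probes differ in sign. Other values that moved by over 1.5 times were as follows, and the cause was not tested unless stated.

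With replicate as a block, which removes spread shared by same-number arrays, the genotype difference counted 1657 higher and 1095 lower in mock and 1385 and 1196 in inoculated plants; 4539 fell in WT, 1969 rose and 1543 fell in CA-YDA, and the interaction counted 354. All genes called without the block were called with it. Normexp correction gave 519 and 337, 441 and 385, 1539 falls in WT, 160 falls in CA-YDA and 9 in the interaction, and the authors' value table gave 462 and 317, 416 and 375, 1471, 145 and 4. At an adjusted p under 0.01 the numbers were 564 and 294, 422 and 305, 831 falls in WT, 735 rises and 32 falls in CA-YDA, and 23. Requiring 2-fold left 1269 falls in WT and 207 in CA-YDA. Measured on all 12 arrays, so with fewer genes tested, 654 were higher and 395 lower in mock, 395 lower in inoculated plants and 33 in the interaction; the genotype overlap was 303 higher and 213 lower, and 292 genes were higher in CA-YDA mock and rose in WT. With no filter 165 fell in CA-YDA and the interaction counted 68. Fitting only the 2 groups compared gave 382 lower in mock and 134 falls in CA-YDA. With an estimated correlation 0 of the list tests passed, against 33 after quantile normalization, 39 with the replicate block and 40 with no filter.

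Leaving out each array in turn gave 743 to 951 higher and 385 to 515 lower in mock, 500 to 714 and 363 to 527 in inoculated plants, 1910 to 2698 rises and 942 to 2990 falls in WT, 775 to 1247 and 53 to 354 in CA-YDA, and 33 to 144 in the interaction; without a replicate number, 33 to 39 list tests passed. Without replicate 1 of every group the counts were 979 and 568, 719 and 554, 2944 and 3501, 1363 and 432, and 95. With slide as a block they were 1006 and 592, 771 and 616 (random), 2702 and 2844, 1347 and 462, and 143 (fixed). Among named genes, those no longer called numbered 66 in the authors' table, 58 with normexp, 32 without replicate 1, 21 with only the 2 groups, 19 with no filter, 13 with the mean of probes, 8 with quantile normalization, and 3 or fewer with the other settings that kept all arrays, among genes still tested; single arrays left out ended 233 calls over all genes and arrays. Newly called named genes numbered 5 with the replicate block, and 2 or fewer with each other setting that kept all arrays. Signal over background limits the genes above it on fewer than 3 arrays of a group, whose log2 changes rest on dim values.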

Other observations

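Of the tests in this part, only the count of neighbouring genes for the first definition of the genotype pattern was set before its result was seen; all others were chosen afterwards. Members of several gene families rose or fell after inoculation more often than other genes. Families of at least 15 tested genes, formed by the start of the symbol, were tested for an excess of called genes with a one-sided Fisher's exact test, 59 families and 472 tests, of which 23 passed after adjustment. The test takes genes as independent, which genes read on the same arrays are not. No correlation between genes was estimated for it, so its adjusted p can be too small. In WT, 35 of 59 WRKY transcription factor genes rose (adjusted p = 1.69e-13), with WRKY51 at 7.10 and WRKY75 at 6.98, and so did 24 of 42 receptor-like protein genes (RLP, adjusted p = 5.8e-09), 18 of 30 cysteine-rich receptor kinase genes (CRK, adjusted p = 3.53e-07), with CRK13 at 5.75, and 19 of 52 NAC genes (adjusted p = 0.000888). Genes of small-molecule chemistry were also among those that rose: 26 of 51 UGT glycosyltransferase genes (adjusted p = 2.24e-08), 13 of 23 GSTU glutathione transferase genes (adjusted p = 6.74e-05), with GSTU12 at 7.40, and 38 of 142 CYP genes (adjusted p = 0.000848), with CYP71A12 at 7.65, while 22 CYP genes fell and the CYP median was -0.197. Of the same families 7 RLP, 4 UGT, 2 NAC, 1 WRKY, 1 CRK and 1 GSTU genes fell. In CA-YDA 24 WRKY, 20 UGT, 14 RLP, 10 GSTU, 11 CRK and 25 CYP genes rose, each with an adjusted p of 2e-04 or less, and 8 CYP, 1 GSTU and 1 CRK genes fell. NAC genes rose for 7 and fell for 1 in CA-YDA, which did not pass as a family.

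Genes of 3 further families formed by symbol, AGP, XTH and PIP, fell in WT more often than other genes. The PIP set also holds genes that share only the letters, such as PIP5K9. Of 27 arabinogalactan protein genes (AGP) 15 fell (adjusted p = 2.75e-05), with AGP41 at -2.14, while AGP5 and AGP23 rose. Of 22 xyloglucan-modifying XTH genes 11 fell (adjusted p = 0.00183), with XTH19 at -2.18, while XTH25 (3.01), XTH29, XTH12 and XTH30 rose, and of 19 genes with a PIP symbol, mostly aquaporins, 11 fell (adjusted p = 0.000359), with PIP1;4 at -1.28, and 0 rose. In CA-YDA 5 AGP and 4 XTH genes fell (adjusted p = 0.00287 and 0.0145), and 2 and 1 rose; 1 PIP gene fell, which did not pass as a family. Between the genotypes, CYP genes were more often higher in CA-YDA, 24 in mock-treated and 17 in inoculated plants (adjusted p = 2.75e-05 and 0.00208), with 8 lower in each, as were 8 RLP genes in mock (adjusted p = 0.0303), with 3 lower. GSTU genes were higher for 6 and lower for 2 of 23 in mock (adjusted p = 0.0223 for higher), and higher for 3 and lower for 6 in inoculated plants (adjusted p = 0.00206 for lower). GSTU4 and GSTU26 were higher and GSTU23 and GSTU24 lower in both. The genotype counts rest on the brightest probe of each gene, and other probes often did not follow large genotype differences, as given below. Part of each excess may therefore not lie in transcript level. Family medians kept their sign under quantile, normexp and the authors' scaling, except that of GSTU in mock, which was -0.012 and turned to 0.007 in the authors' table.

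Replicate 1 differed from replicates 2 and 3 in every group. The heat shock factor gene HSFA2 was lower (-6.49), as were 10 of 17 genes with an HSP symbol, with HSP17.6A at -4.87, HSP101 at -4.29, HSP90.1 at -4.14 and HSP70 at -3.81. The clock gene PRR9 (-5.81) and the light-stress gene ELIP1 (-3.97) were lower too. BT2 (4.88), the auxin gene IAA29 (3.28), BBX14 (3.08) and BBX27 (2.52) were higher. Among the fixed lists, with group as a term in the model, 17 jasmonate genes (adjusted p = 7.19e-08), 16 pattern-triggered immunity genes (adjusted p = 1.33e-06) and 11 abscisic acid genes (adjusted p = 1.59e-05) were lower in replicate 1, and 13 cell division genes (adjusted p = 5.52e-07) and 6 stomatal lineage genes (adjusted p = 0.0317) were higher. Salicylic acid (adjusted p = 0.000241), tryptophan-derived (adjusted p = 0.000451) and detoxification genes (adjusted p = 0.0139) also moved down, with 9, 8 and 5 lower and 1 salicylic acid gene higher. These values are for the preset correlation, with which 8 of 21 lists passed; with an estimated correlation 0 did, and the adjusted p was 0.229 for jasmonate, pattern-triggered immunity and cell division genes and 0.157 for abscisic acid genes.

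In all, 2010 genes were higher and 2072 lower in replicate 1. A difference between slides is argued against: replicates 1 and 2, which share slides, differed at 2414 genes, and replicates 2 and 3, which do not, at 0 in limma (1742 at an unadjusted p under 0.05). A difference in temperature or heat stress between experiments may be a candidate explanation, since 10 of 17 genes with an HSP symbol were lower (camera p = 2.68e-10, and p = 0.000517 with an estimated correlation), though the pattern was found on the same data. A difference in time of day stays open, as 5 of 14 clock genes passed, 2 higher and 3 lower. Growth conditions per experiment were not given.

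Large genotype differences that held with and without the fungus were examined under 2 definitions. The first took 145 genes not above background in 1 genotype under both treatments, 67 higher and 78 lower in CA-YDA: other kept probes moved along in 18 of 21 genes, 85.7%, against 21 of 25, 84%, for genes switched by PcBMM in WT, which by the bound set for it would count against a sequence difference under the probe. That test was judged void afterwards and decides nothing, since a gene with a brighter probe that still read in both genotypes could not enter this set. Up to 6 of them lay among 100 neighbouring tested genes, against a median of 5 and a 95th percentile of 6 in random sets, which decides nothing, and the slides of a genotype differed by 0.323 at the median against 4.03 between genotypes. The second definition, chosen after that result, took 461 probes over 4-fold apart in both treatments: all kept probes followed in 65 of 172 genes, 37.8%, against 274 of 312, 87.8%, for probes changed by PcBMM, the busiest window held 12 genes against a 95th percentile of 10 and a highest of 12 in random sets, and slides differed by 0.322 against 3.54. On chromosomes 1 to 5 the busiest windows of this second set held 12, 11, 11, 11 and 10 genes. For the probes whose sister probes did not follow, sequence differences between the lines, possibly in part in chromosome segments, may be a candidate explanation, though the labels give La-0 for both lines. At genes whose kept probes did not all follow, 37.8% against 87.8% argues against a level difference shared by all transcripts of the gene. The small slide differences decide nothing, since both sets were chosen by a test whose spread includes slide differences within a genotype. Slide effects stay open, untested. So do true differences in transcript level between the genotypes at genes whose kept probes all followed or that had only 1.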
